A study of Mus musculus with 36 samples.

How the data were processed

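Total RNA from mouse knee joints was extracted with TRIzol, depleted of ribosomal RNA and, for the set analysed here, sequenced as paired-end reads of 100 bp on a DNBSEQ-G400, per the labels' protocols. The series holds 36 libraries in 3 sets. The first set has 9 libraries in 3 groups of 3 biological replicates: sham knees without injury of the anterior cruciate ligament (ACL), injured knees of mice given saline vehicle, and injured knees of mice given a protein kinase C (PKC) inhibitor. All were collected at 24 h. The other 2 sets, a time course after injury and a comparison of PKC, LATS and YAP/TAZ inhibitors, were not analysed here, because the 27 columns of their count tables carry codes that match no sample label. Comparisons within and between those sets were therefore not run.

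The deposited table of the first set holds raw read counts per gene name. Its columns were given to samples by their names alone, which match the sample titles. Their order differs from that of the alignment files in the command recorded in the file header. Every group value rests on the names. Counts were made with featureCounts 2.0.1 for read pairs on the reverse strand over the exons of GENCODE M25, per the file headers, with multi-mapping reads counted in full at every location and reads over several genes counted for each of them. HISAT2, of a version not given in the sources used here, and the mm10 build are named in the submitters' processing notes. Counting in this way inflates families of near-identical genes, above all those of 7SL RNA, and lets overlapping genes and close paralogues share reads. Such genes are named as uncertain. Coordinates are the first and last exon base of each gene on mm10, per the file headers, counted from 1. No gene of the mitochondrial chromosome had a count in any library, so mitochondrially encoded genes were not compared. Nuclear gene models that resemble mitochondrial genes, such as Gm28661 and Gm10925, held 8.65% (vehicle 3) to 25.0% (sham 3) of counts outside the 7SL genes. Whether these reads came from mitochondrial transcripts was not tested.

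All further steps were run here on the deposited counts with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 in Python 3.11.15. Of 55291 genes in the table, 28362 were never counted in these libraries and 13823 passed edgeR's filterByExpr. The 9 libraries were scaled by the trimmed mean of M values (TMM) and fitted together with robust quasi-likelihood dispersions, with a mean per group. Each comparison is a two-sided quasi-likelihood F test, adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p of a gene comes from this edgeR test unless DESeq2 is named, and every standard error (SE) of a log2 fold change is the fold change divided by the square root of its F statistic. The SE of a list median is instead computed from the SD and number of its members, so it does not measure spread between libraries. A normalised count is the count divided by the library's effective size and multiplied by the mean effective size. It is given as mean ± SD. A fold against a group without a count is a lower bound computed against 3 counts per library. For a gene with 1 to 3 counts in a group, the ratio of summed counts is given with a 95% exact binomial interval scaled by effective library sizes, which covers counting error only.

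The following was fixed before the data were examined: the comparisons of injury with sham and of inhibitor with vehicle, their tests, most of the alternatives, the rule for naming genes, and 27 gene lists. The lists are YAP/TAZ-TEAD targets, PKC and Hippo pathway components, immediate-early genes, inflammatory cytokines and mediators, matrix proteases, cartilage, osteoblast and osteocyte, osteoclast, fibrous matrix and myofibroblast, synovial and connective tissue fibroblast, tendon and ligament, neutrophil, monocyte and macrophage, B lineage, T and NK cell, erythroid, skeletal muscle, adipocyte, endothelial, epidermal keratinocyte, Schwann cell and nerve, cell cycle, hypoxia and glycolysis, interferon-stimulated, p53 target and senescence, oxidative phosphorylation and unfolded protein response genes. Egr1 and Egr2 each stand in a pair of lists. Lists with at least 3 tested members were compared with all other genes by limma's camera on log2 CPM (counts scaled to library size, prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the 26 lists so tested. The T and NK cell list had 2 tested members and was not tested. Beside each list call stands the adjusted p of camera with an estimated correlation. The smallest such value was 0.241 for injury against sham, 0.538 for inhibitor against vehicle and 0.22 for inhibitor against sham, so no list call held with an estimated correlation. A count of list members is given over all genes tested and adjusted over the list alone.

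Genes were named if they belonged to a set of focus genes (among them Ccn1, Ccn2, Ankrd1, Il6, Il1b, Cxcl1, Ptgs2, Mmp3, Mmp13, Adamts4, Adamts5, Timp1, Acan, Col2a1 and Prg4; not all are reported here), if they were among the 4 members with the smallest p in the direction of a called list, or if they were among the 8 largest changes each way. The last kind had to have an adjusted p under 0.05, at least 1 CPM in the higher group, no overlap between the libraries of both groups, and a symbol other than a gene model, pseudogene or antigen receptor segment. Genes named outside this rule are said to be chosen after their values were seen.

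Total counts ran from 124 to 202 M per library, but counts outside the 7SL genes from 3.28 to 11.9 M and counts on protein-coding genes, as typed in GENCODE M21, from 1.09 to 4.51 M. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom from 16.6 to 203), so none was treated as a duplicate. Pearson's r of log2 CPM between libraries ran from 0.844 to 0.938. The workflow was tested on simulated counts with 200 changed genes, drawn 5 times for each comparison. For injury against sham it recovered 12.8% of the genes changed 2-fold, 66.9% of those changed 4-fold and 77.3% of those changed 8-fold (12996 genes tested). For inhibitor against vehicle the shares were 15.2%, 66.0% and 87.3% (13074 genes tested), and for inhibitor against sham 15.8%, 69.9% and 87.3% (13132 genes tested). False calls made up 7.61%, 8.35% and 8.0% of all calls, each above the threshold of 0.05. A list of 15 doubled genes passed camera, at an unadjusted p under 0.05, in 5 of 5 simulations of each comparison. Simulated genes were drawn independently of each other. In the real lists the estimated correlation ran from −0.018 (p53 target genes) to 0.938 (skeletal muscle genes). These simulations therefore do not test list calls whose members vary together. Draws of the same kind with the sham and vehicle means of the data called 210 to 258 genes higher with injury, against 39 in the data. The recovered shares thus apply to simulated counts and may overstate recovery in the real libraries.

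Alternatives were size factors by relative log expression (RLE), DESeq2, no filter on low counts, a filter of at least 1 CPM in 3 libraries, fits of only the compared groups, the replicate number as a term, the mean log2 CPM of the skeletal muscle list as a covariate, and leaving out each library in turn. Added after the data were seen were the comparison of inhibitor with sham, a fit of protein-coding genes alone, a correction for GC content (a smooth trend with 4 degrees of freedom per library on the GC content of the longest GENCODE M21 transcript, known for 98.3% of tested genes), the omission of inhibitor libraries 1 and 2, the sum of 5S ribosomal RNA copies, and the simulations of shared control libraries.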

Results

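Knee joint tissue of mice was profiled by RNA sequencing 24 h after injury of the anterior cruciate ligament (ACL), a ligament that stabilises the knee and whose injury is a frequent start of post-traumatic osteoarthritis. The study targeted protein kinase C (PKC), a family of lipid-activated kinases, and the Hippo pathway, a kinase cascade that restrains the transcriptional coactivators YAP and TAZ. The libraries described here came from 3 sham knees without ACL injury, 3 injured knees of mice given saline vehicle and 3 injured knees of mice given a PKC inhibitor. They answer which genes differ 24 h after injury, and which of them differ when PKC is inhibited.

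Total counts ran from 124 to 202 M per library, but most fell on the genes of 7SL RNA, the RNA of the signal recognition particle. Its share was 97.2%, 97.1% and 97.0% in sham libraries 1 to 3, 98.1%, 96.7% and 97.9% in the vehicle libraries, and 91.5%, 91.2% and 98.2% in the inhibitor libraries. Counts outside the 7SL genes therefore ran from 3.28 M (vehicle 1) to 11.9 M (inhibitor 1). The small nucleolar RNA U3 took 9.03% (sham 3) to 53.2% (inhibitor 1) of these. Protein-coding genes held 1.09 to 4.51 M counts, and 17758 to 21397 genes had at least 1 count. Nemf, a ribosome quality control factor, had 1177819 counts in sham 1 and 45 to 195 in the other libraries. Skeletal muscle genes, a measure of muscle left on the joint, averaged 2.24, 2.43 and 3.47 log2 CPM in the sham libraries, 1.90, 1.28 and 1.74 in the vehicle libraries and 4.11, 0.45 and 1.43 in the inhibitor libraries.

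**Figure D1:**
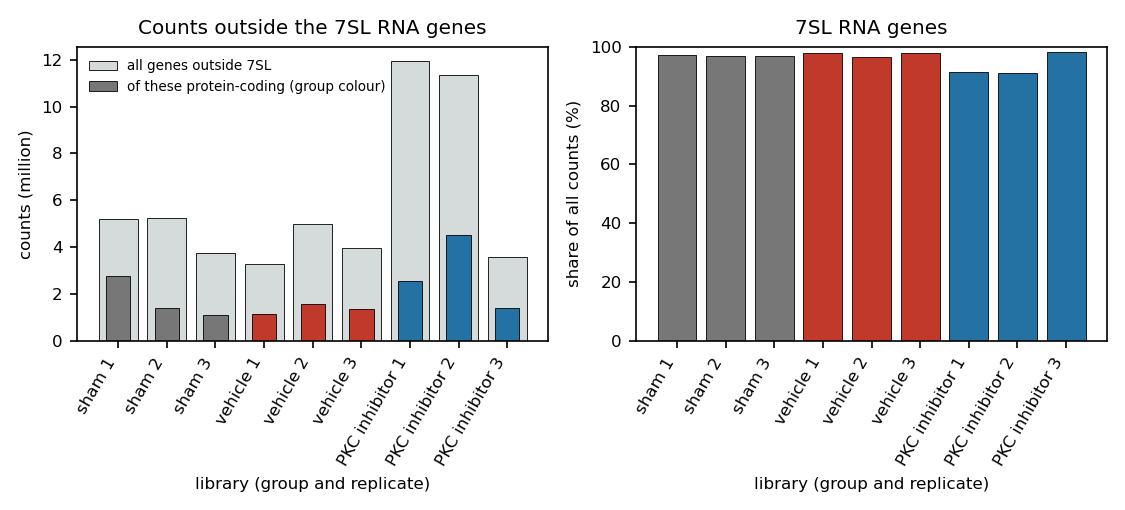
Counts per library outside the 7SL genes (left, M counts; light bars all genes, coloured bars protein-coding genes) and the 7SL share of all counts (right, percent) in 3 sham, 3 vehicle and 3 PKC inhibitor libraries. Inhibitor libraries 1 and 2 held 11.9 and 11.4 M counts outside 7SL, and the other 7 libraries 3.28 to 5.25 M.

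At 24 h after injury, Serpina3n, Ccl7 and Ankrd1 were among the genes with higher transcript levels and Ltf among those with lower ones. Serpina3n, a secreted protease inhibitor of the acute-phase response, was 9.37-fold higher in injured vehicle knees than in sham knees (302 ± 119 against 31.6 ± 9.01 normalised counts, SD, n = 3 each, adjusted p = 0.000553). Ccl7, a chemokine that attracts monocytes, had 223 counts over the vehicle libraries and 1 over the sham libraries, a ratio of 221 with a counting interval of 39.2 to 8753 (adjusted p = 0.00475). Ankrd1, a target gene of YAP and TAZ that is also induced in stressed muscle, was 15.8-fold higher (53.3 ± 24.6 against 3.34 ± 0.885, adjusted p = 0.0209). Ltf, which encodes the neutrophil granule protein lactoferrin, was 2.67-fold lower (769 ± 173 against 2053 ± 646, adjusted p = 0.0288).

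These genes lie on mm10 at chromosome 12 from 104406729 to 104414329 (Serpina3n), chromosome 11 from 82045712 to 82047525 (Ccl7), chromosome 19 from 36111961 to 36120099 (Ankrd1) and chromosome 9 from 111019271 to 111042767 (Ltf). Serpina3n belongs to a cluster of close paralogues that can share reads, so its level is uncertain to that extent. In all, 42 of 13823 tested genes differed, 39 higher and 3 lower with injury, all of them protein-coding and all by more than 2-fold. The balance of directions depended on the setting, with 125 higher and 30 lower in DESeq2, 164 and 98 with no filter, 170 and 121 with only the compared groups in the fit, and 108 and 90 with the muscle covariate. It was 150 and 84 without inhibitor 1, and 177 and 124 without inhibitor 1 and 2 together. DESeq2 called 155 genes, and 1145 had an unadjusted p under 0.05 by edgeR. In 17.0% of tested genes the libraries of both groups did not overlap, against 10% by chance. The 3 lower genes were Ltf, Cybb, the catalytic subunit of the phagocyte NADPH oxidase (135 ± 7.46 against 300.2 ± 34.7, 2.22-fold, adjusted p = 0.0356; chromosome X from 9435252 to 9487771), and the macrophage lectin Mgl2, which was chosen after its values were seen (4.12 ± 1.17 against 46.9 ± 10.5, log2 fold change −3.46, SE 0.63, adjusted p = 0.0288).

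Inflammatory cytokines and mediators formed the list with the largest median change. Of 18 measured members, 17 had a positive log2 fold change, 2 rose over all genes tested and 12 rose when adjusted over the list alone. Its median log2 fold change was 4.13, or 2.995 with 2 genes uncounted in sham set at their bound (camera adjusted p = 5.29e-19; adjusted p = 0.241 with an estimated correlation). Ccl2, Ccl4, Ccl7, Cxcl1, Cxcl2, Cxcl5 and Lif had only 1 to 3 counts over the sham libraries, so the size of either median is uncertain. Beside Ccl7, the neutrophil chemokine Cxcl2 rose, with 252 counts against 2, a ratio of 125 and an interval of 34.2 to 1035 (adjusted p = 0.0356; chromosome 5 from 90903871 to 90905938). The monocyte chemokine Ccl2 had 218 counts against 2 (ratio 108, interval 29.5 to 896, adjusted p = 0.0682), and Lif, a cytokine of the interleukin-6 family, 50 against 1 (ratio 49.5, interval 8.48 to 1992, adjusted p = 0.0588).

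Immediate-early genes, transcribed soon after a stimulus, moved up as a list (median log2 fold change 1.33, 17 of 18 positive, camera adjusted p = 1.91e-12; adjusted p = 0.241 with an estimated correlation). Over all genes tested 3 of them rose, and 10 when adjusted over the list alone. Maff, a small transcription factor of the stress response, was at 69.0 ± 22.9 against 12.9 ± 6.37 (log2 fold change 2.34, SE 0.41, adjusted p = 0.0288; chromosome 15 from 79346621 to 79359076). Fos, a component of the AP-1 transcription factor, was 3.46-fold higher (122 ± 35.5 against 35.5 ± 7.26, adjusted p = 0.0288; chromosome 12 from 85473890 to 85477273). Fosl1, another AP-1 component, had no count in sham and was at least 5.16-fold higher (22.5 ± 3.83, adjusted p = 0.0356). Junb was at 334 ± 107 against 78.1 ± 14.1 (adjusted p = 0.12).

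Neutrophil genes moved down as a list (median log2 fold change −0.72, 3 of 16 positive, camera adjusted p = 0.000551; adjusted p = 0.606 with an estimated correlation). Ltf alone fell over all genes tested, and 7 genes fell when adjusted over the list alone. Other granule genes were at 1308 ± 140 against 3146 ± 786 (Ngp, adjusted p = 0.0548) and at 298 ± 40.7 against 718 ± 284 (Camp, adjusted p = 0.0694). Prtn3, a protease of immature neutrophils, had a log2 fold change of −1.05 (adjusted p = 0.196). Monocyte and macrophage genes moved up as a list, with a small median (0.24, 13 of 18 positive, mean 0.70, camera adjusted p = 0.0163; adjusted p = 0.606 with an estimated correlation) and none passing alone over all genes or over the list. Its member Arg1, an arginine-degrading enzyme of wound macrophages, was at 655 ± 299 against 5.24 ± 5.23 (log2 fold change 6.77, SE 1.52, adjusted p = 0.232). Ccr2, the receptor of Ccl2 and Ccl7, had a log2 fold change of 1.28 (adjusted p = 0.292), Fcgr1 one of 1.71 (adjusted p = 0.325) and Spp1, which overlaps a gene model, one of 0.87 (adjusted p = 0.443).

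All 16 skeletal muscle genes had a negative log2 fold change (median −1.10, camera adjusted p = 0.000685; adjusted p = 0.606 with an estimated correlation), none past the threshold alone. Myoglobin (Mb) had a log2 fold change of −2.10 (SE 0.95, adjusted p = 0.638) and skeletal actin (Acta1) one of −1.24 (adjusted p = 0.736). The per-library muscle level differed among sham knees as well, with 3.47 log2 CPM in sham 3 against 2.24 in sham 1. Adipocyte genes followed the same direction (median −1.06, 1 of 10 positive, camera adjusted p = 0.00169; adjusted p = 0.606 with an estimated correlation). Log2 fold changes were −2.10 for the lipid droplet gene Cidec (adjusted p = 0.408) and −0.90 for adiponectin (Adipoq, adjusted p = 0.629). Cell cycle genes had a median of −0.38 with all 18 negative (camera adjusted p = 0.00356; adjusted p = 0.606 with an estimated correlation). They included the mitotic kinase Aurka at −0.69 (adjusted p = 0.401) and Birc5 at −0.64 (adjusted p = 0.522).

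Among focus genes besides Ankrd1, several lay higher in all injured libraries without passing the test. Timp1, an inhibitor of matrix metalloproteases, was at 358 ± 91.1 against 32.4 ± 1.17 (log2 fold change 3.46, SE 0.57, adjusted p = 0.0577; chromosome X from 20870166 to 20874735). Prg4, which encodes the joint lubricant lubricin, was at 5648 ± 1076 against 1121 ± 669 (adjusted p = 0.135; chromosome 1 from 150449412 to 150466165). The YAP and TAZ targets Ccn2 and Ccn1 were at 237 ± 29.4 against 130.0 ± 16.4 (adjusted p = 0.127; chromosome 10 from 24595442 to 24598683), and at 110 ± 10.1 against 57.3 ± 6.57 (adjusted p = 0.179; chromosome 3 from 145646976 to 145649981). Stromelysin (Mmp3) was at 103 ± 33.4 against 8.42 ± 12.4 (adjusted p = 0.269). The prostaglandin synthase Ptgs2 was at 60.9 ± 39.4 against 7.46 ± 3.35 (adjusted p = 0.2). The aggrecanase Adamts4 was at 54.7 ± 12.8 against 17.4 ± 10.7 (adjusted p = 0.252) and Il1b at 271 ± 112 against 80.6 ± 10.5 (adjusted p = 0.653). Cxcl1 had 126 counts against 3, a ratio of 41.6 and an interval of 13.9 to 204 (adjusted p = 0.235). The other aggrecanase Adamts5 (log2 fold change 0.21, adjusted p = 0.919), the collagenase Mmp13 (0.35, adjusted p = 0.86), aggrecan (Acan, −0.67, adjusted p = 0.78) and type II collagen (Col2a1, −0.66, adjusted p = 0.816) overlapped between the groups. Il6, with 30 counts over all libraries, was below the filter.

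Among called genes of at least 1 CPM, the largest changes also included the chemokines Cxcl14, Pf4, Ccl6 and Ccl9. Cxcl14 was at 353 ± 121 against 84.8 ± 13.4 (log2 fold change 2.06, SE 0.28, adjusted p = 0.00583) and platelet factor 4 (Pf4) at 232 ± 86.7 against 59.8 ± 5.43 (adjusted p = 0.0134). Ccl6 was at 771 ± 229 against 182 ± 35.5 (adjusted p = 0.015) and Ccl9 at 249 ± 95.2 against 61.1 ± 7.5 (adjusted p = 0.0288). Metallothionein 1 (Mt1), a metal-binding protein, rose to 885 ± 342 from 142 ± 25.2 (adjusted p = 0.0356). The fibronectin receptor subunit Itga5 rose to 215 ± 37.0 from 61.5 ± 21.2 (adjusted p = 0.0196). The lipid droplet coat gene Plin2 rose to 554 ± 183 from 143 ± 26.2 (adjusted p = 0.0247).

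The list of YAP/TAZ-TEAD targets had a median log2 fold change of 0.03 and a mean of 0.42, with 10 of 20 positive (camera adjusted p = 0.0559; adjusted p = 0.47 with an estimated correlation), and did not pass. It passed in 5 alternatives: with the muscle covariate (median 0.17, adjusted p = 0.0154), with no filter (0.0355), with protein-coding genes alone (median −0.05, 0.0465), without sham 3 (0.0291) and without vehicle 1 (0.0239). Ankrd1 rose over all genes tested, and 4 members when adjusted over the list alone. PKC and Hippo pathway components did not pass (median −0.07, 10 of 23 positive, camera adjusted p = 0.977), nor did matrix proteases (median 0.28, 5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.154) or cartilage genes (median −0.62, 3 of 18 positive, camera adjusted p = 0.0992). The protease list passed without sham 3 (adjusted p = 0.0291) and with only the compared groups in the fit (0.0477), and the cartilage list without sham 2 (adjusted p = 0.00504) and with a replicate block (0.0347). Leaving out sham 1, 2 or 3 left 1, 1 and 16 called genes, leaving out vehicle 1, 2 or 3 left 2, 22 and 4, and only Serpina3n kept its call throughout, while 234, 86 and 301 genes were called without inhibitor library 1, 2 or both. The calls of the monocyte and macrophage list (adjusted p = 0.0842, 0.0749 and 0.254 without sham 1, sham 2 and vehicle 3) and of the cell cycle list (0.138 and 0.0947 without sham 1 and vehicle 1) ended without a single library. Called medians also moved for immediate-early genes (0.80 without vehicle 1), for neutrophil and muscle genes (−0.36 and −0.58 without sham 3), and for monocyte and macrophage genes (0.38, 0.44 and 0.01 without sham 3, vehicle 2 and vehicle 3).

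**Figure D2:**
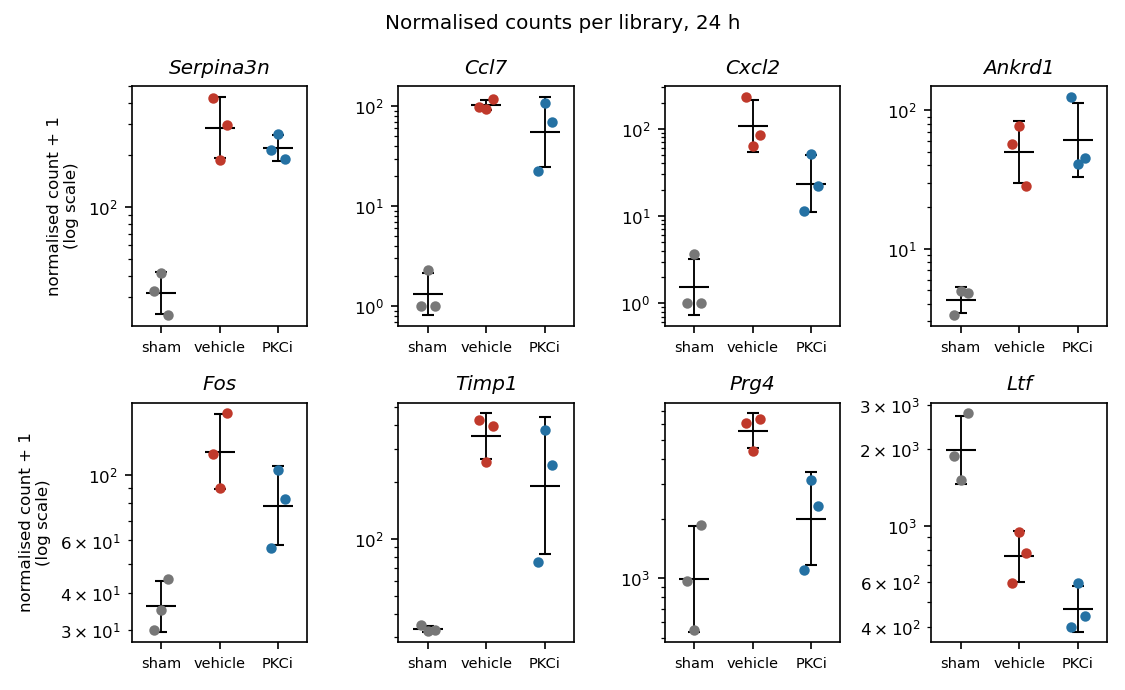
Normalised counts plus 1 on a log axis for Serpina3n, Ccl7, Cxcl2, Ankrd1, Fos, Timp1, Prg4 and Ltf in sham, vehicle and PKC inhibitor libraries; points are libraries, bars geometric means and whiskers 1 SD of log2 values (n = 3). Serpina3n averaged 31.6 in sham, 302 with vehicle and 220.3 with the inhibitor, and Ltf 2053, 769 and 476.

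Against vehicle, most genes that differed in knees of mice given the PKC inhibitor lay lower, among them Cd22, Srrm2 and Safb2. Cd22, an inhibitory receptor of B cells, was 4.88-fold lower (15.1 ± 6.86 against 72.8 ± 23.7 normalised counts, SD, n = 3 each, adjusted p = 0.0234). Srrm2, a scaffold protein of nuclear speckles, was 2.83-fold lower (763 ± 166 against 2155 ± 693, adjusted p = 0.0233), and Safb2, a nuclear scaffold attachment factor, 3.23-fold lower (288 ± 118 against 925 ± 67.2, adjusted p = 0.0277). Cbr2, a carbonyl reductase, was higher (183 ± 10.9 against 73.1 ± 8.63, log2 fold change 1.32, SE 0.22, adjusted p = 0.0233).

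Cd22 lies at chromosome 7 from 30865402 to 30880342, Srrm2 at chromosome 17 from 23790532 to 23824741, Safb2 at chromosome 17 from 56560965 to 56584585 and Cbr2 at chromosome 11 from 120729489 to 120732114. Of 13823 tested genes, 101 differed, 97 lower and 4 higher with the inhibitor. This balance was 305 lower and 50 higher in DESeq2, 379 and 175 with no filter, 269 and 45 with the muscle covariate, 50 and 23 without inhibitor 2, and 15 and 5 without inhibitor 1 and 2 together. DESeq2 called 355, and 1858 genes had an unadjusted p under 0.05 by edgeR. In 18.9% of tested genes the libraries of both groups did not overlap, against 10% by chance. The called genes included 77 protein-coding genes and 13 near-identical copies of 5S ribosomal RNA, and 14 overlapped another gene on the same strand. Reads of the 5S copies cannot be assigned to a copy, so these 13 calls can rest on the same reads. Beside Cbr2, the 4 higher genes were Slfn5, of the interferon-inducible Schlafen family (369.9 ± 102 against 175 ± 2.76, log2 fold change 1.08, SE 0.22, adjusted p = 0.0386), and Scamp1 (60.6 ± 7.29 against 19.7 ± 4.28, adjusted p = 0.0461) and Taf13 (59.6 ± 9.06 against 19.3 ± 4.86, adjusted p = 0.0497), the last pair chosen after their values were seen.

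Among called genes of at least 1 CPM, other large decreases were found in Ccdc88c, Plcb2, Tnfrsf14, Ppox, Csf2ra and Pabpn1. Ccdc88c, a regulator of Wnt signalling, was at 147 ± 33.1 against 429 ± 81.3 (log2 fold change −1.55, SE 0.25, adjusted p = 0.0211; chromosome 12 from 100911523 to 101029056). The phospholipase Plcb2 was at 129.9 ± 29.8 against 341 ± 85.3, the lymphocyte receptor Tnfrsf14 at 77.6 ± 20.8 against 204 ± 49.7 and the haem synthesis enzyme Ppox at 123 ± 64.7 against 388 ± 63.8 (each adjusted p = 0.0234). Csf2ra, a subunit of the receptor for granulocyte-macrophage colony-stimulating factor, was at 154 ± 65.1 against 478 ± 63.2 (adjusted p = 0.0292). Pabpn1, a nuclear poly(A)-binding protein that overlaps a gene model, had a log2 fold change of −1.38 (adjusted p = 0.0308).

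Cartilage genes moved down as a list (median log2 fold change −1.002, 1 of 18 positive, camera adjusted p = 3.35e-08; adjusted p = 0.591 with an estimated correlation). None fell over all genes tested, and 4 when adjusted over the list alone. The type IX collagen chain Col9a1 was at 41.2 ± 12.4 against 146 ± 15.8 (log2 fold change −1.86, SE 0.41, adjusted p = 0.0688; chromosome 1 from 24177610 to 24252684), and the type XI chain Col11a2 at 772 ± 452 against 2384 ± 18.1 (adjusted p = 0.128). Type II collagen (Col2a1), the main fibrillar collagen of cartilage, was at 1410 ± 891 against 5654 ± 1291 (log2 fold change −2.01, SE 0.56, adjusted p = 0.162; chromosome 15 from 97975602 to 98004695). Sox6, a transcription factor of chondrocytes, had a log2 fold change of −0.80 (adjusted p = 0.0984). B lineage genes moved the same way (median −1.12, 2 of 10 positive, camera adjusted p = 0.000156; adjusted p = 0.538 with an estimated correlation). Cd22 fell over all genes tested, and 5 members when adjusted over the list alone. Those not passing over all genes included the antigen receptor chain Cd79a (17.1 ± 9.09 against 51.5 ± 14.8, adjusted p = 0.0984) and Cd79b (log2 fold change −1.50, adjusted p = 0.138).

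Inflammatory cytokines and mediators, higher with injury, had a negative median with the inhibitor (−0.69, 2 of 18 positive, camera adjusted p = 0.0002; adjusted p = 0.649 with an estimated correlation), none passing alone over all genes or over the list. Cxcl2 was at 27.2 ± 20.6 against 125 ± 92.1 (log2 fold change −2.13, SE 0.66, adjusted p = 0.196), and the chemokine Ccl4 had a log2 fold change of −2.47 (adjusted p = 0.31). Osteoblast and osteocyte genes (median −0.44, 1 of 14 positive, camera adjusted p = 0.00177; adjusted p = 0.677 with an estimated correlation) moved down. Among them were the parathyroid hormone receptor Pth1r at −0.86 (adjusted p = 0.148) and the bone matrix gene Dmp1 at −1.23 (adjusted p = 0.429). Keratinocyte genes, present in skin, had a median of −1.07 with 1 of 8 positive (camera adjusted p = 0.00177; adjusted p = 0.591 with an estimated correlation). Krt1 was at 5.07 ± 4.89 against 26.7 ± 8.93 (adjusted p = 0.151). All 18 cell cycle genes were negative (median −0.32, camera adjusted p = 0.00339; adjusted p = 0.695 with an estimated correlation). Among them were Mki67 at −1.56 (adjusted p = 0.191) and Plk1 at −0.74 (adjusted p = 0.243). All 12 unfolded protein response genes were negative (median −0.39, camera adjusted p = 0.00339; adjusted p = 0.591 with an estimated correlation), among them Creld2 at −0.80 (adjusted p = 0.299).

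Erythroid genes (median −0.55, 1 of 11 positive, camera adjusted p = 0.0404; adjusted p = 0.695 with an estimated correlation) and neutrophil genes (median −0.26, 4 of 16 positive, camera adjusted p = 0.0415; adjusted p = 0.695 with an estimated correlation) lay close to the threshold. Their members with the smallest p were Epb42 at −0.84 (adjusted p = 0.253) and myeloperoxidase (Mpo) at −0.93 (adjusted p = 0.149). Genes of oxidative phosphorylation moved up, with all 16 positive and a median of 0.45 (camera adjusted p = 0.00118; adjusted p = 0.649 with an estimated correlation). They included Ndufs1 at 0.82 (adjusted p = 0.183) and Cox6c at 0.62 (adjusted p = 0.19). Tendon and ligament genes also moved up (median 0.89, 9 of 10 positive, camera adjusted p = 0.00935; adjusted p = 0.649 with an estimated correlation), 2 of them when adjusted over the list alone. Col14a1 was at 134 ± 92.6 against 37.7 ± 10.6 (adjusted p = 0.155), tenomodulin (Tnmd) had a log2 fold change of 2.34 (adjusted p = 0.197) and the tendon transcription factor Scx one of 1.56 (adjusted p = 0.255).

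YAP/TAZ-TEAD targets did not move one way as a list (median 0.07, mean 0.03, test direction down, 11 of 20 positive, camera adjusted p = 0.969). Ccn1 was at 70.0 ± 9.41 against 110 ± 10.1 (log2 fold change −0.66, SE 0.24, adjusted p = 0.238), Ccn2 at 168 ± 16.8 against 237 ± 29.4 (−0.50, SE 0.20, adjusted p = 0.278) and Ankrd1 at 69.3 ± 47.2 against 53.3 ± 24.6 (0.38, SE 0.46, adjusted p = 0.764). PKC and Hippo pathway components had a median of 0.27 with 16 of 23 positive (camera adjusted p = 0.221). Prg4 was at 2188 ± 1034 against 5648 ± 1076 (adjusted p = 0.243) and Acan at 163 ± 103 against 334 ± 45.1 (adjusted p = 0.399). The other focus genes had log2 fold changes of −1.28 (Cxcl1, adjusted p = 0.572), −1.16 (Ptgs2, adjusted p = 0.491), −1.13 (Mmp3, adjusted p = 0.576) and −0.61 (Timp1, adjusted p = 0.621). For Il1b it was −0.59 (adjusted p = 0.79), −0.40 (Mmp13, adjusted p = 0.647), −0.01 (Adamts4, adjusted p = 0.995) and 0.09 (Adamts5, adjusted p = 0.933).

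None of the 101 calls held in every fit with a library left out, where 42, 0 and 8 genes were called without vehicle 1, 2 and 3 (1301 genes had an unadjusted p under 0.05 without vehicle 2), 256 without inhibitor 3, 41 without sham 1, 20 without inhibitor 1 and 2 together (9 of the 101 among them), 46 after GC correction, 3 when only vehicle and inhibitor were fitted, and none among 2703 genes of at least 1 CPM in 3 libraries (544 at an unadjusted p under 0.05). List calls ended without inhibitor 1 (inflammatory, adjusted p = 0.0863; osteoblast, 0.0977; cell cycle, 0.624; erythroid, 0.416; neutrophil, 0.517), inhibitor 2 (erythroid, 0.0596), inhibitor 3 (tendon, 0.245; neutrophil, 0.223), vehicle 1 (neutrophil, 0.136), vehicle 2 (cell cycle, 0.063; erythroid, 0.745) or vehicle 3 (neutrophil, 0.0598), without inhibitor 1 and 2 together (oxidative phosphorylation, 0.183; osteoblast, 0.195; cell cycle, 0.791; erythroid, 0.977), or with at least 1 CPM in 3 libraries (unfolded protein response, 0.0953; tendon, 0.416; neutrophil, 0.416; erythroid, 0.0704), while those of cartilage, B lineage and keratinocyte genes held in every alternative run. B lineage and keratinocyte genes had fewer than 3 tested members with at least 1 CPM in 3 libraries, so their calls were not tested under that filter. Without inhibitor 1 the called medians became −0.34 for inflammatory, −0.25 for osteoblast, −0.31 for erythroid, −0.02 for neutrophil, 0.03 for cell cycle and 0.24 for oxidative phosphorylation genes. Without inhibitor 2 they became −1.65 for inflammatory, −0.28 for osteoblast, −0.74 for neutrophil and −0.50 for cell cycle genes. Without inhibitor 3 they became −1.01 for osteoblast, −0.85 for erythroid and 0.20 for tendon genes. Without vehicle 1 they became −0.69 for osteoblast and −0.52 for cell cycle genes. Without vehicle 2 they became −0.41 for neutrophil, −0.17 for erythroid and −0.16 for cell cycle genes.

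**Figure D3:**
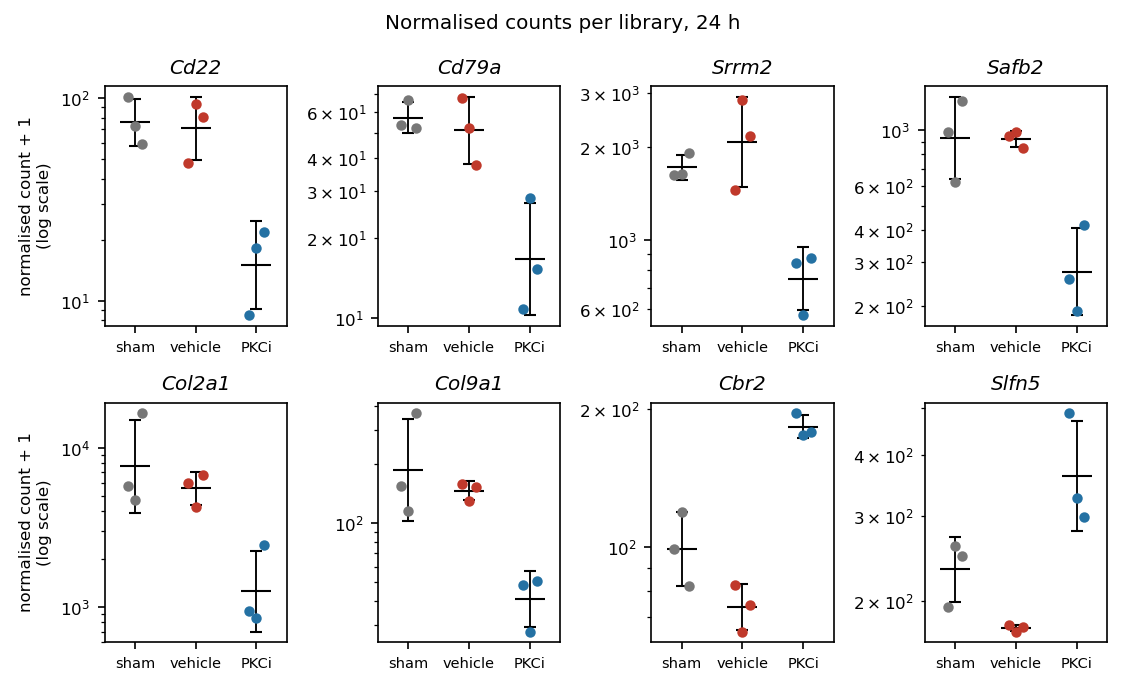
Normalised counts plus 1 on a log axis for Cd22, Cd79a, Srrm2, Safb2, Col2a1, Col9a1, Cbr2 and Slfn5 in sham, vehicle and PKC inhibitor libraries; points are libraries, bars geometric means and whiskers 1 SD of log2 values (n = 3). Cd22 averaged 76.9 in sham, 72.8 with vehicle and 15.1 with the inhibitor, and Col2a1 8949, 5654 and 1410.

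Injured knees with the PKC inhibitor were also set against sham knees, a comparison chosen after the data were seen. Serpina3n was 6.88-fold higher (220.3 ± 39.1 against 31.6 ± 9.01 normalised counts, SD, n = 3 each, adjusted p = 0.0012) and Ankrd1 20.5-fold higher (69.3 ± 47.2 against 3.34 ± 0.885, adjusted p = 0.00321). Lactoferrin (Ltf) was 4.31-fold lower (476 ± 102 against 2053 ± 646, adjusted p = 0.00216). Type II collagen (Col2a1) was 6.35-fold lower (1410 ± 891 against 8949 ± 6479.6, adjusted p = 0.0366).

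A total of 546 genes differed, 175 higher and 371 lower. DESeq2 called 885, and 2482 genes had an unadjusted p under 0.05 by edgeR. In 22.9% of tested genes the groups did not overlap, against 10% by chance. After GC correction the split was 191 higher and 252 lower. The calls included 473 protein-coding genes and 25 copies of 5S ribosomal RNA, which can rest on the same reads, and 56 overlapped another gene on the same strand. The genes named for their increase included Ccl7, Ccl2 and Lif. Ccl7 had 357 counts against 1 (ratio 165, interval 29.3 to 6518, adjusted p = 0.00321). Ccl2 had 344 against 2 (ratio 79.3, interval 21.8 to 657, adjusted p = 0.0301) and Lif 92 against 1 (ratio 42.4, interval 7.42 to 1693, adjusted p = 0.0268). Log2 fold changes were 2.07 for Cxcl14, 2.19 for Ccl6 and 2.13 for Medag, which overlaps a gene model (each adjusted p = 0.00321), 2.32 for Mt1 (adjusted p = 0.0175) and 3.17 for Mt2 (adjusted p = 0.0349). Timp1 was at 232 ± 152 against 32.4 ± 1.17 (log2 fold change 2.84, SE 0.56, adjusted p = 0.0306). Among called genes of at least 1 CPM, the largest decreases included Tspoap1 (−3.21, adjusted p = 0.0237) and the mitotic kinesin Kifc1 (−2.09, adjusted p = 0.0378). Beside them stood the type X collagen of hypertrophic cartilage Col10a1 (229 ± 68.5 against 965 ± 698, adjusted p = 0.0415) and the myeloid adaptor Card9 (−2.04, adjusted p = 0.0434).

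Cartilage genes moved down as a list with none of 18 positive (median −1.48, camera adjusted p = 5.51e-09; adjusted p = 0.438 with an estimated correlation). Of these 6 fell over all genes tested and 12 when adjusted over the list alone, among them Col9a1 (41.2 ± 12.4 against 210.5 ± 134, adjusted p = 0.0111), Col11a2 (log2 fold change −2.03, adjusted p = 0.0314) and Sox6 (180 ± 45.7 against 343 ± 4.71, adjusted p = 0.0245). B lineage genes were likewise all negative (median −1.23, camera adjusted p = 4.69e-07; adjusted p = 0.22 with an estimated correlation), with 4 lower over all genes tested and 7 adjusted over the list alone. Cd22 had a log2 fold change of −2.37 (adjusted p = 0.00617), Cd79a one of −1.66 (adjusted p = 0.0334) and Cd79b one of −1.68 (adjusted p = 0.045). Neutrophil genes moved down (median −0.95, 3 of 16 positive, camera adjusted p = 5.46e-06; adjusted p = 0.438 with an estimated correlation), 6 of them over all genes tested and 9 adjusted over the list alone. Mpo was at 331 ± 36.7 against 1078 ± 475 (adjusted p = 0.00623), and Prtn3 and Camp had log2 fold changes of −1.69 (adjusted p = 0.00744) and −1.44 (adjusted p = 0.0105). Cell cycle genes were all negative (median −0.71, 2 of 18 lower over all genes tested and 10 adjusted over the list alone, camera adjusted p = 4.69e-07; adjusted p = 0.438 with an estimated correlation). Ccnb2 was at −1.24 (adjusted p = 0.0382) and Plk1 at −1.07 (adjusted p = 0.0387).

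Inflammatory cytokines and mediators moved up (median 2.82, or 2.51 with 2 genes uncounted in sham at their bound, 17 of 18 positive, camera adjusted p = 4.69e-07; adjusted p = 0.438 with an estimated correlation), 3 of them over all genes tested and 7 adjusted over the list alone. The size of this median is uncertain too, since several members had only 1 to 3 counts over the sham libraries. Immediate-early genes also moved up (median 1.30, 14 of 18 positive, 5 over all genes tested and 9 over the list alone, camera adjusted p = 1.14e-05; adjusted p = 0.438 with an estimated correlation). Maff had a log2 fold change of 2.43 (adjusted p = 0.00587), Atf3 one of 2.62 (adjusted p = 0.0197) and Egr1 one of 1.61 (adjusted p = 0.048). Fosl1, uncounted in sham, was at least 2.74-fold higher (adjusted p = 0.0222). Monocyte and macrophage genes had a median of 0.60 with 16 of 18 positive (camera adjusted p = 0.000776; adjusted p = 0.438 with an estimated correlation), and Cd68 rose to 207 ± 58.7 from 92.2 ± 23.0 (adjusted p = 0.0236). The p53 target and senescence list had a median of 0.45 with 6 of 9 positive (camera adjusted p = 0.0245; adjusted p = 0.438 with an estimated correlation), and its cell cycle inhibitor Cdkn1a rose to 269 ± 43.6 from 117 ± 25.6 (adjusted p = 0.0095).

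Osteoblast and osteocyte genes (median −0.84, none of 14 positive, camera adjusted p = 0.000203; adjusted p = 0.455 with an estimated correlation) and erythroid genes (median −0.88, none of 11 positive, camera adjusted p = 0.000814; adjusted p = 0.438 with an estimated correlation) moved down with no member past the threshold over all genes. Keratinocyte genes had a median of −1.48 with 2 of 8 positive (camera adjusted p = 0.0254; adjusted p = 0.455 with an estimated correlation), and Krt1 fell (log2 fold change −3.10, adjusted p = 0.02). Adipocyte genes (median −0.46, camera adjusted p = 0.0475; adjusted p = 0.64 with an estimated correlation) and skeletal muscle genes (median −0.24, mean 0.03, test direction down, camera adjusted p = 0.0468; adjusted p = 0.694 with an estimated correlation) lay at the threshold. YAP/TAZ-TEAD targets had a median of 0.32 with 14 of 20 positive (camera adjusted p = 0.0845; 0.0426 without sham 3, 0.0487 with no filter and 0.0486 after GC correction), and 3 of them rose, among them Ankrd1. Cxcl2 had 159 counts against 2 (ratio 36.6, interval 9.98 to 305, adjusted p = 0.0541) and Cxcl1 144 against 3 (ratio 22.1, interval 7.42 to 109, adjusted p = 0.172). Log2 fold changes of the other focus genes were 0.28 (Ccn1, adjusted p = 0.604), 0.36 (Ccn2, adjusted p = 0.379), 0.97 (Prg4, adjusted p = 0.325) and −1.73 (Acan, adjusted p = 0.0987). They were 1.14 (Il1b, adjusted p = 0.526), 2.70 (Mmp3, adjusted p = 0.206), −0.05 (Mmp13, adjusted p = 0.956), 1.69 (Adamts4, adjusted p = 0.0698), 0.29 (Adamts5, adjusted p = 0.668) and 1.90 (Ptgs2, adjusted p = 0.239).

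Without sham 1, 2 or 3 the count was 141, 259 and 153, without inhibitor 1 or 2 it was 841 and 281, without vehicle 3 it was 307, without inhibitor 1 and 2 together 174, and 98 of the 546 calls held in every fit with a library of either group left out. List calls ended without sham 1 (keratinocyte, adjusted p = 0.172), sham 2 (p53 target, 0.069), sham 3 (skeletal muscle, 0.329; adipocyte, 0.231), inhibitor 2 (keratinocyte, 0.0589; p53 target, 0.0597; skeletal muscle, 0.989; adipocyte, 0.192) or inhibitor 3 (skeletal muscle, 0.23; adipocyte, 0.324), without inhibitor 1 and 2 together (osteoblast, 0.546; erythroid, 0.299; p53 target, 0.0541), or with at least 1 CPM in 3 libraries (monocyte and macrophage, 0.125; p53 target, 0.306; adipocyte, 0.92; skeletal muscle, 0.214). They also ended with only the compared groups in the fit (p53 target, 0.0792; skeletal muscle, 0.0913; adipocyte, 0.0586), with the muscle covariate (keratinocyte, 0.0539; skeletal muscle, 0.711; adipocyte, 0.423), with protein-coding genes alone (skeletal muscle, 0.0579; adipocyte, 0.0938) or in DESeq2 (adipocyte, 0.0504). Called medians became 1.61 for inflammatory, −0.53 for osteoblast and 0.25 for p53 target genes without inhibitor 2, and −0.55 for osteoblast, −1.44 for adipocyte, −1.75 for skeletal muscle and 0.72 for p53 target genes without inhibitor 1. Without sham 3 they became −0.96 for cartilage, −0.53 for neutrophil, −0.19 for adipocyte and 0.28 for skeletal muscle genes, without sham 1 −0.81 for keratinocyte and −0.49 for skeletal muscle genes, and without sham 2 −0.41 for skeletal muscle genes. Without inhibitor 3 they became −1.29 for osteoblast, 0.38 for monocyte and macrophage, −0.22 for adipocyte and 0.11 for skeletal muscle genes.

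Of the 42 genes called with injury, edgeR in the fit of all libraries called none between inhibitor and vehicle (smallest adjusted p 0.0516, for Mgl2), and 39 were called again between inhibitor and sham. In alternatives this did not hold for Cxcl2. It passed as lower with the inhibitor than with vehicle in 2 of 9 other settings and in 0 of 6 fits with a library left out. Its log2 fold change there ran from −3.05 to −1.37. Among the 39 genes higher with injury, 26 lay lower and 13 higher with the inhibitor than with vehicle, and 3 had all inhibitor libraries under all vehicle libraries. Their median log2 fold change, inhibitor against vehicle, was −0.16, and by library −0.55, 0.10 and −0.16 from the vehicle mean. Both comparisons share the vehicle libraries, and 30 simulations with an unchanged inhibitor group show what this alone brings. The median of the 39 top genes ran from −0.34 to −0.05 there, with 51.3% to 74.4% of genes lower against 66.7% observed. The simulations called 210 to 258 genes higher with injury, more than the data, and the median over these ran from −0.27 to −0.160, against −0.155 observed. Of these genes 65.7% to 74.9% lay lower. Across genes, which are not independent replicates, and with simulations in which no group changed, Pearson's r of the log2 fold changes was −0.380 (simulated −0.534 to −0.494), Spearman's rho −0.336 (simulated −0.498 to −0.469) and the covariance −0.164 (simulated −0.133 to −0.117). Of 39 genes higher with injury and 175 higher with the inhibitor against sham, 37 were shared, and of 3 and 371 lower genes 2 were shared. Independent lists of these sizes would share 0.494 and 0.0805 genes, and unchanged groups against the same sham libraries shared 10 to 20 top genes in simulations. With 3 vehicle and 3 sham libraries the controls cannot be split into groups of at least 2, so part of the overlap may come from the shared libraries.

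**Figure D4:**
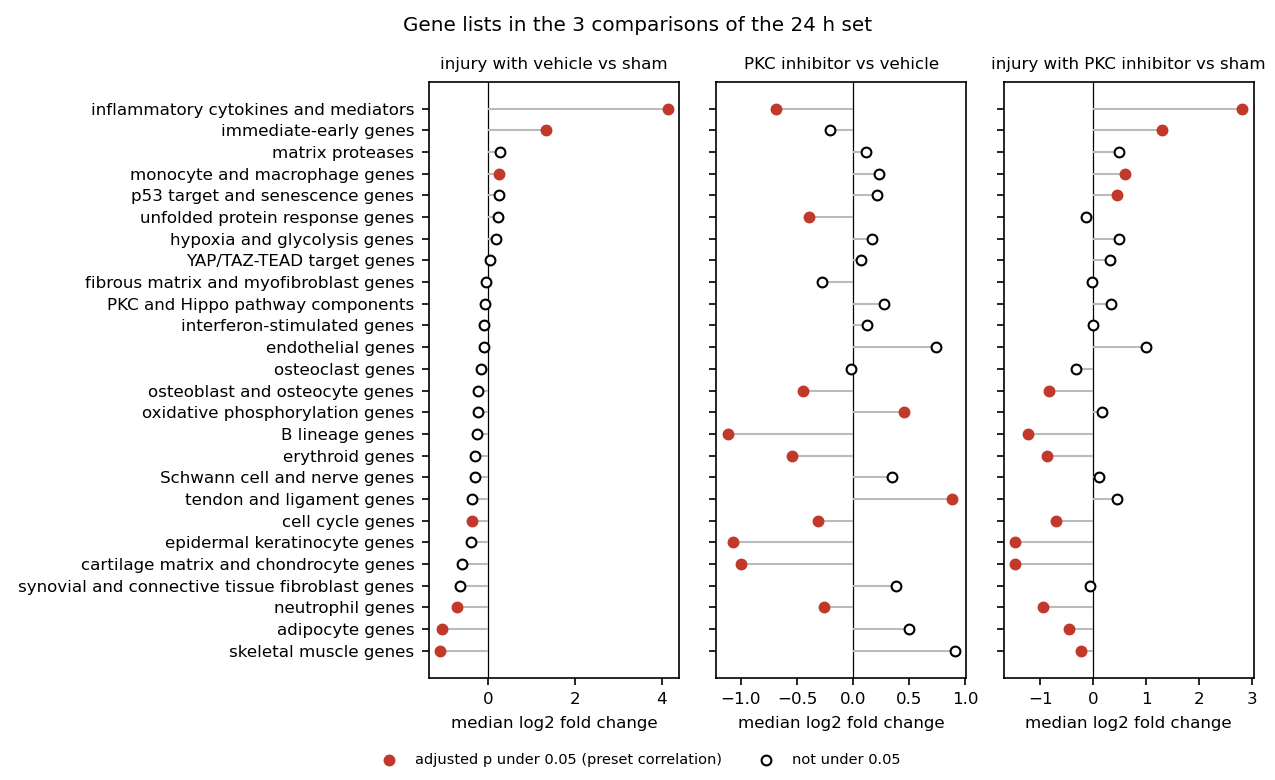
Median log2 fold change of each gene list in the comparisons of vehicle with sham, inhibitor with vehicle and inhibitor with sham; filled points have a camera adjusted p under 0.05 with the preset correlation. Inflammatory mediators had medians of 4.13, −0.69 and 2.82, and cartilage genes of −0.62, −1.002 and −1.48.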

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

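The comparison of inhibitor with sham, the fit of protein-coding genes alone, the GC correction and the omission of inhibitor libraries 1 and 2 were chosen after the data were seen; all other alternatives were planned. No called gene of any comparison changed sign in any alternative, but the counts of called genes moved. For injury against sham (42), inhibitor against vehicle (101) and inhibitor against sham (546) they were 42, 100 and 540 with RLE factors and 43, 77 and 547 with protein-coding genes alone; 155, 355 and 885 with DESeq2; 262, 554 and 1056 with no filter; 25, 0 and 399 with at least 1 CPM in 3 libraries, where 2703 genes were tested; 291, 3 and 198 with only the compared groups in the fit; 198, 314 and 1221 with the skeletal muscle covariate; 39, 46 and 443 after GC correction; and 301, 20 and 174 without the inhibitor libraries of low 7SL share. Leaving out a library of the compared groups gave 1 to 22, 0 to 256 and 141 to 841 calls. Under the stricter filter, which kept only well-counted genes, 32 of the 101 genes called between inhibitor and vehicle were still tested and none passed. The smaller number of genes alone therefore does not account for that fall. The cause of these shifts was not tested.

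With the replicate block as a term the counts were 24, 103 and 420, and cartilage (median −0.42) and p53 target genes (0.23) passed with injury (adjusted p = 0.0347 each). Libraries of the same number did not deviate together (r from −0.241 to 0.0694, median −0.0168, against a median of 0.00693 for other pairs), and not every library correlated best with its own number, so no pairing is assumed.

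Of the called lists 3 of 7, 3 of 11 and 6 of 13 kept their call in every alternative run, and of the lists not called 12 of 19, 5 of 15 and 7 of 13 passed in at least 1 alternative. Immediate-early, inflammatory, B lineage and keratinocyte genes were not tested with at least 1 CPM in 3 libraries, where fewer than 3 members were left. With injury, calls ended with at least 1 CPM in 3 libraries for monocyte (0.213), adipocyte (0.241) and cell cycle genes (0.0715), and with the muscle covariate for monocyte (0.0529) and adipocyte genes (0.183). With the inhibitor against vehicle, the calls of erythroid and neutrophil genes ended with the muscle covariate (0.0581 and 0.072) and after GC correction (0.0696 each). The skeletal muscle covariate turned the test direction of muscle genes with injury, by construction (median 0.00385, adjusted p = 0.855), and of endothelial genes (0.57). Without the inhibitor libraries of low 7SL share, the test direction turned against vehicle for osteoblast (median 0.18), erythroid (−0.10) and endothelial genes (−0.68), and against sham for osteoblast (0.11) and endothelial genes (−0.95). Leaving out a library, medians ran against vehicle from −0.70 to 1.33 for muscle and −0.40 to 1.17 for endothelial genes, and against sham from −1.75 to 0.28 for muscle and −0.77 to 1.43 for endothelial genes, the test direction turning where inhibitor 1 or 2 was left out; the cause was not tested. By fry, which asks whether the genes of a list move one way on balance, the smallest adjusted p was 0.0649 with injury and 0.081 with the inhibitor against vehicle, while B lineage (0.00897) and p53 target genes (0.0491) passed against sham. Fry's test for change in either direction gave other results. With injury it passed for lists including YAP/TAZ-TEAD targets (adjusted p = 2.98e-07), p53 targets (4.89e-05), matrix proteases (0.000727) and unfolded protein response genes (0.000779). For inhibitor against vehicle it passed for B lineage (0.00636), PKC and Hippo (0.0304) and YAP/TAZ-TEAD genes (0.0373). Passing it does not show a common direction.

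Few of the simulated 2-fold changes were recovered (12.8% with injury), and Il6, with 30 counts in all, could not be compared. Comparisons, gene lists, signature tests and correlations of the other sets were not run.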

Other observations

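Chosen only after the results were seen were the comparison of inhibitor with sham, the GC correction, the fit of protein-coding genes alone, the 5S sum, the tests of the monocyte and macrophage list and of the shared vehicle libraries, and the genes Mgl2, Il33, Pdpn, Lox, Msr1, Scamp1, Taf13, Rpph1, Rmrp and Rn7sk.

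The summed 5S ribosomal RNA, Rpph1, Rmrp and Rn7sk had lower mean counts with the inhibitor than with vehicle, and none passed the edgeR test of that comparison. The 181 copies of 5S ribosomal RNA, summed because their reads cannot be told apart, were at 3855 ± 1094 normalised counts in sham, 2596 ± 1496 with vehicle and 453 ± 256 with the inhibitor (SD, n = 3 each). A multi-mapping read was counted at every location, so the sum can hold the same read several times. It is not a number of reads, and its test treats repeats as separate counts. The libraries were depleted of ribosomal RNA, and whether depletion differed between them was not tested. The sum did not pass against vehicle in edgeR (log2 fold change −2.51, SE 0.59, adjusted p = 0.125; from 2.65e-05 in DESeq2 to 0.271 over the alternatives, and 0.028 without inhibitor 3) and fell against sham (−3.09, SE 0.60, adjusted p = 0.0345), a call that ended without sham 1 (0.0779), sham 2 (0.0753), sham 3 (0.108), inhibitor 1 (0.0506) or inhibitor 2 (0.0919), with no filter (0.0806) and with the muscle covariate (0.0752). Without inhibitor 1 and 2 together the log2 fold change of the sum was −4.01 against vehicle and −4.57 against sham. With injury alone the sum was at −0.57 (adjusted p = 0.862), and from −1.13 without vehicle 2 to −0.32 without vehicle 1. Rpph1, the RNA of RNase P, was at 112837 ± 13646 with vehicle and 35519.5 ± 27525 with the inhibitor (adjusted p = 0.176), Rmrp at 37049 ± 10649 and 17915 ± 5979 (adjusted p = 0.353), and Rn7sk at 52762 ± 8969 and 27844 ± 7943 (adjusted p = 0.283).

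Pdpn, Il33, Lox and Msr1 rose with injury. Pdpn, a surface protein of activated synovial fibroblasts, rose to 180.5 ± 40.8 from 10.9 ± 2.74 (log2 fold change 4.05, adjusted p = 0.0196), the alarmin Il33 to 87.7 ± 4.40 from 10.2 ± 5.10 (3.04, adjusted p = 0.00583), the collagen crosslinking enzyme Lox to 441 ± 52.5 from 197 ± 39.2 (1.17, adjusted p = 0.0415) and the scavenger receptor Msr1 to 107 ± 21.4 from 9.64 ± 1.89 (3.44, adjusted p = 0.00583). The lectin Mgl2, lower with injury, was at 30.6 ± 19.1 with the inhibitor (against vehicle 2.82, SE 0.63, adjusted p = 0.0516).

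Lists not described above gave, for injury against sham, inhibitor against vehicle and inhibitor against sham, these median log2 fold changes with camera adjusted p, none with a call in the fit of all libraries: fibrous matrix −0.05 (mean 0.42, test direction up, 0.189), −0.28 (0.25) and −0.03 (mean 0.36, test direction up, 0.761); synovial fibroblast −0.65 (0.174), 0.39 (0.577) and −0.05 (mean 0.12, 0.761); and osteoclast −0.17 (0.174), −0.02 (0.567) and −0.33 (0.104). Endothelial genes had −0.11 (0.712), 0.74 (0.367) and 1.01 (0.599), Schwann cell genes −0.32 (0.351), 0.35 (0.198) and 0.11 (0.599), hypoxia genes 0.19 (0.108), 0.17 (0.577) and 0.49 (0.0561), and interferon-stimulated genes −0.10 (0.343), 0.12 (0.54) and 0.00 (mean −0.12, 0.911). With injury, the other medians were −0.23 for osteoblast (0.343), −0.37 for tendon (0.174), −0.27 for B lineage (0.0559), −0.30 for erythroid (0.0992), −0.40 for keratinocyte (mean −0.03, test direction up, 0.843), 0.24 for p53 target (0.0714), −0.24 for oxidative phosphorylation (0.0597) and 0.23 for unfolded protein response genes (0.0584). With the inhibitor against vehicle they were −0.20 for immediate-early (0.0799), 0.12 for matrix protease (0.781), 0.23 for monocyte and macrophage (0.252), 0.91 for skeletal muscle (0.367), 0.50 for adipocyte (0.469) and 0.21 for p53 target genes (0.367), and against sham 0.33 for PKC and Hippo (0.236), 0.48 for matrix protease (0.11), 0.45 for tendon (0.236), 0.16 for oxidative phosphorylation (0.155) and −0.13 for unfolded protein response genes (0.435).

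Many of these lists passed in some alternative. With injury and the muscle covariate these were B lineage (0.00277), erythroid (0.00357), endothelial (median 0.57, 0.0005), hypoxia (0.0108) and p53 target genes (0.0372). With no filter they were B lineage, oxidative phosphorylation and unfolded protein response genes (0.0355 each), with protein-coding genes alone B lineage and oxidative phosphorylation genes (0.0465 each), with only the compared groups B lineage genes (0.0432), and with at least 1 CPM in 3 libraries unfolded protein response genes (0.00239). Without sham 3 they were fibrous matrix, B lineage (0.0291 each), erythroid, oxidative phosphorylation (0.0353 each), hypoxia, unfolded protein response (0.0314 each) and p53 target genes (0.0378). Without vehicle 1 they were osteoclast (0.0281), B lineage (0.0236) and oxidative phosphorylation genes (0.00219), and without vehicle 2 erythroid (0.00159), p53 target and unfolded protein response genes (0.0431 each).

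With the inhibitor against vehicle, muscle genes passed in opposite directions without inhibitor 1 (−0.70, 0.00111) and inhibitor 2 (1.33, 0.000252), and so did endothelial genes without inhibitor 1 (−0.40, 0.0136), without inhibitor 1 and 2 together (−0.68, 0.0102) and without inhibitor 3 (1.16, 0.0167). Immediate-early genes passed with no filter (0.0399) and without vehicle 2 (0.00677) or inhibitor 2 (0.00788), monocyte and macrophage genes without vehicle 3 (0.022) or inhibitor 1 (0.0129), and fibrous matrix genes without inhibitor 3 (0.035). Against sham, endothelial genes passed with the muscle covariate (1.06, 0.000968) and the other way without inhibitor 1 (−0.77, 0.00707) or inhibitor 1 and 2 together (−0.95, 0.00296). Tendon genes passed there without inhibitor 2 (0.89, 0.0219) or inhibitor 1 and 2 together (1.11, 0.00101), and their median ran from −0.35 to 0.89 with a library left out. Hypoxia genes passed with no filter (0.0316), with the muscle covariate (0.02) and without sham 3 (0.0138) or inhibitor 3 (0.00844), matrix protease genes without sham 3 (0.0138), osteoclast genes with no filter (0.0487) and oxidative phosphorylation genes with the muscle covariate (0.0495).

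One pattern is the predominance of lower genes with the inhibitor against vehicle, 97 of 101, a share of 96.0% that fell to 68.4% with no filter and 68.5% without inhibitor 2. A GC trend between libraries is argued against as its whole cause, since 44 of the 46 genes called after GC correction lay lower (95.7%). The median log2 fold change of the 97 lower genes was −1.55 (SD 0.73) before and −1.49 (SD 0.72) after GC correction. These genes were selected for lying low, so their median is a weak test. Only 44 of the 97 stayed called, with edgeR adjusted p up to 0.157 and a median SE of 0.29 in place of 0.28. The lower genes were GC-rich, with a median of 56.15% against 49.84% for all tested genes, so a part played by GC content stays open. Scaling by 7SL and other abundant RNAs stays open: with protein-coding genes alone the protein-coding ones had a median of −1.36 (−1.35 before), but all genes shared by both fits shifted by a median of only −0.02, so this setting moved too little to test it. A smaller number of B cells in the sampled tissue stays open: the B lineage median was −1.12 (SE 0.32, over members and not libraries), between no change and that of the called genes, and 1 of its members was among them. Whether such a difference came from the animals or from the tissue taken was not tested. The real grouping called 101 genes and the highest of the other splits 0 by edgeR (1858 and at most 926 genes at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05, which holds for every comparison here.

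Another pattern is that 39 of 42 genes called with injury were higher, which holds for this fit and not for others: lower genes made up 7.14% here, but 37.4% with no filter, 41.6% with only the compared groups, 45.5% with the muscle covariate, 35.9% without inhibitor 1 and 41.2% without inhibitor 1 and 2 together. What follows covers these 39 genes only. A GC trend is argued against, since their median log2 fold change was 1.96 before and 1.98 after GC correction (SD 2.04 both times, 35 of 39 still called). The genes were selected for their change, so this median is a weak test. Of all genes called after the correction, 37 lay higher and 2 lower. Whether a larger number of monocytes and macrophages accounts for the 39 higher genes stays open. Their list had a median of 0.24 (SE 0.48, over members and not libraries), with none of its 18 members called. That median lay below that of the called genes by more than this SE. The list still went up, with 13 of 18 positive and a mean of 0.70. The called genes were selected for their change and the list was not, so the gap between the medians cannot decide the question. The response of resident joint cells to injury, which the design names, was not tested apart from other causes and stays open. The real grouping called 42 genes and the highest of the other splits 0 (1145 and at most 701 at an unadjusted p under 0.05), and for inhibitor against sham 546 and 0 (2482 and at most 1433).

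A further pattern is that 26 of the 39 genes higher with injury lay lower with the inhibitor than with vehicle. This share of 66.7% lay within both ranges simulated with an unchanged inhibitor group, 51.3% to 74.4% for the 39 top genes and 65.7% to 74.9% for all genes called there. The shared vehicle libraries alone can thus give such a share, but whether they account for it here stays open. The median of the 39 genes, −0.155, lay within the range simulated for the 39 top genes (−0.34 to −0.05). It lay just above that for all genes called there (−0.27 to −0.160), and the simulations called 210 to 258 genes where the data gave 39. In neither range did the observed median lie below what an unchanged inhibitor group gave, and a small effect of the inhibitor on these genes is not excluded.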
